A study of Sus scrofa with 5 samples.

How the data were processed

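Single-nucleus RNA sequencing libraries were made from the abdominal aortae of 5 castrated male Ossabaw pigs, of which 3 had been fed a high-fat, high-fructose diet (obese group) and 2 a chow diet (control group). Each library came from 1 pig, so the pig was the unit of replication. The labels place the start of the diet at 12 months of age, and give its duration as 6 months in one place and 9 months in another. A piece of frozen vessel of about 50 mm was dissociated per sample, and nuclei stained with DRAQ5 were sorted before droplet capture with 10x Genomics 3' chemistry. The deposited values are raw UMI counts per gene and barcode made by the authors with Cell Ranger. The labels give version 5.0 of that program and the file headers version 7.1.0, and the pig genome build is named as Sscrofa11. Seurat 5.0 is named for later steps that the count matrices do not show. The values were checked to be whole numbers, and the lowest total of any listed barcode was 500 UMIs.

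The matrices held 35670 features, of which 17508 carried a gene symbol in the files. A table of gene identifiers named 220 more, and 17942 features kept only an identifier and were tested but not named. Barcodes with at least 300 detected genes and at most 5% mitochondrial UMIs were kept, which removed 77 of 45580 barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked 2 barcodes in all 5 libraries together, so the highest-scoring barcodes up to the expected rate were removed instead, 3522 in all, a choice made after seeing that count. Removed barcodes had a median of 2390, 2077 and 1685.5 UMIs in obese replicates 1 to 3, against 1807.5, 2253 and 1869 in kept nuclei. In control replicates 1 and 2 the medians were 3053.5 and 3301.5, against 2681 and 2452. Some removed barcodes may therefore not be doublets. The remaining 41981 nuclei held 143643012 UMIs. Counts were scaled to 10000 UMIs per nucleus and log-transformed, 3000 variable genes and 30 principal components were taken, and nuclei were joined to their 20 nearest neighbours and clustered with leidenalg 0.10.2 at a resolution of 1.0 with seed 1, in Python 3.11.15.

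The 25 clusters were named from fixed marker lists. A marker counted when its CPM in the cluster was at least 20 and at least 2 times its 25th percentile over clusters. A class name needed at least 3 such markers and a mean marker position of at least 0.4 between that percentile and the highest cluster. That threshold of position was set after the values were seen. A name was withheld where at least 3 genes of the kidney tubule were among the leading genes of a cluster. It was also withheld where UMIs were low with no marker of the class among the leading genes, or where another class had more markers there. Names end in "-like", since they rest on markers alone. Clusters 3, 11 and 18 were left unnamed.

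For each class with at least 20 nuclei in every pig, counts were summed per pig and obese pigs were compared with control pigs by the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by diet group and Benjamini-Hochberg adjustment over the genes tested. A gene was called changed at an adjusted p under 0.05. The same test was run over all kept nuclei, and the difference of the diet effect between classes was tested as an interaction with the pig as a block. The design leaves 3 residual degrees of freedom among the pigs, and edgeR pools the spread of genes with a prior. Where leaving out a pig left 1 control pig, that pig was assumed to vary like the obese pigs. Shares of nuclei were compared by an exact two-sided permutation test over the 10 assignments of 5 pigs to 3 and 2, whose smallest p is 0.2, and each pig's share has an exact binomial interval at 95%. Intervals and floors cover counting error only.

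A set of 23 gene lists, fixed before the data were examined, was tested in the 4 main classes with camera of limma 3.58.1, at a preset correlation of 0.01, for lists with at least 5 tested members. This gave 78 tests, adjusted together. Camera with an estimated correlation and fry were run beside it, and none of the 40 lists called at the preset correlation was called with an estimated one. Genes were named by a rule fixed before the data were examined. For each main class it takes the 10 called genes of largest rise and the 10 of largest fall whose pigs do not overlap between groups, filled to 5 by p where fewer were called, and given as values. It also takes up to 4 members per list past an adjusted p of 0.05 over the list alone, or the 2 members of highest expression where none was. In other comparisons it takes 5 genes of each direction. Where the control or obese pigs of a class held 1 to 3 counts of a gene together, a ratio of pooled counts with its counting interval is given in place of a fitted fold, and where they held 0 counts the fold is a lower bound against 3 counts over the group together. That bound takes the mean CPM over the pigs of the other group, so it is not on the scale of the pooled ratios. The test was tried on simulated counts with the same libraries and dispersions. At a simulated log2 fold change of 2 it recovered 81.7% of changed genes in smooth muscle-like sums, 84.7% in fibroblast-like, 86.8% in endothelial-like and 7.98% in macrophage-like sums, and at a log2 fold change of 1 between 0% and 1.04% in these classes. At 2 the false calls numbered 14, 10, 9 and 2 in the same order, beside 156, 155, 165 and 13 recovered genes. At 3 they numbered 19, 15, 17 and 2, beside 183, 183, 185 and 110.

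Alternatives chosen before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter and a stricter filter on low counts (a CPM of 10 in at least 2 pigs), the replicate number as a block, each pig left out, no doublet removal, a stricter filter on nuclei (500 genes, 1% mitochondrial UMIs), a Leiden resolution of 0.5, centring per library before clustering, and a filter on genes below 10% of their highest class. Alternatives chosen after seeing the data were single clusters of a class, the addition of clusters 3 and 18 to smooth muscle-like nuclei, smooth muscle-like nuclei of at least 2000 UMIs, and all nuclei without cluster 11. Lymphatic endothelial-like and B or plasma cell-like nuclei had fewer than 20 nuclei in at least 1 pig and were not tested for genes. Results of 5 single genes are not reported here, while the numbers of genes changed and the list tests include them. Sequence reads were not used here.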

Results

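Nuclei from the abdominal aorta were sequenced for 3 obese pigs on a high-fat, high-fructose diet and 2 control pigs on chow, with 1 library per pig. The labels call the aortae atherosclerotic and healthy, and no lesion measure was used here. Total depth was 22400089, 35655806 and 29717314 UMIs in obese replicates 1 to 3, and 47724416 and 21516249 UMIs in control replicates 1 and 2. After filtering, 7144, 9289 and 9039 nuclei were kept from the obese pigs and 11072 and 5437 from the control pigs. The median was 1807.5, 2253 and 1869 UMIs per nucleus in the obese libraries and 2681 and 2452 in the control libraries. The comparison made throughout is obese minus control, and it asks how each cell class of the aortic wall differed with the diet.

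Smooth muscle-like nuclei were the main class in every pig, with 63.1% ± 5.60 of nuclei in obese pigs (SD, n = 3) and 81.7% ± 1.98 in control pigs (SD, n = 2). Macrophage-like nuclei made up 7.29% ± 6.78 in obese pigs and 0.396% ± 0.0401 in control pigs. They ranged from 1.53% (1.28% to 1.80%) in obese replicate 3 to 14.8% (14.0% to 15.5%) in obese replicate 2, with exact binomial intervals in brackets. The control pigs had 0.425% (0.312% to 0.564%) and 0.368% (0.225% to 0.568%). Endothelial-like nuclei held 2.17% in obese and 3.62% in control pigs, and fibroblast-like nuclei 6.38% and 6.98%. Pericyte-like nuclei held 1.60% and 1.07%, Schwann cell-like nuclei 1.66% and 0.927%, and T or NK cell-like nuclei 0.749% and 0.978%. Lymphatic endothelial-like nuclei held 0.360% and 0.191%, and B or plasma cell-like nuclei 0.199% and 0.378%. No share can pass an exact two-sided permutation test here, whose smallest p is 0.2. That p was reached for smooth muscle-like, macrophage-like, endothelial-like and B or plasma cell-like nuclei (adjusted p = 0.45 over 9 classes). Nuclei were sorted on a DNA stain before capture, so shares describe the captured nuclei. With clusters 3 and 18 added, an alternative chosen after seeing the data, smooth muscle-like nuclei held 76.3% ± 10.2 in obese and 85.0% ± 0.0819 in control pigs. The groups then overlapped (72.3%, 68.6% and 87.9% in obese, 85.1% and 84.9% in control pigs, exact permutation p = 0.6). Without obese replicate 2 the macrophage-like difference was 3.16 percentage points, against 6.89 with all pigs. That pig had 1371 macrophage-like nuclei, and 1771 when nuclei were clustered with no doublet removal. The control pigs had 47 and 20, and 50 and 20 with no doublet removal. The clusters within a class also differed by group. Of the smooth muscle-like clusters, cluster 2 held 19.3% of nuclei in obese and 1.95% in control pigs, and cluster 4 held 0.542% and 20.3%. The unnamed clusters took unequal shares as well, under a naming threshold set after the values were seen. Cluster 3 held 13.1% ± 5.14 of obese and 0.963% ± 0.876 of control nuclei, cluster 11 held 3.33% and 0.469%, and cluster 18 held 0.0531% and 2.37%, the latter from 4.44% in control replicate 1 and 0.294% in control replicate 2.

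**Figure D1:**
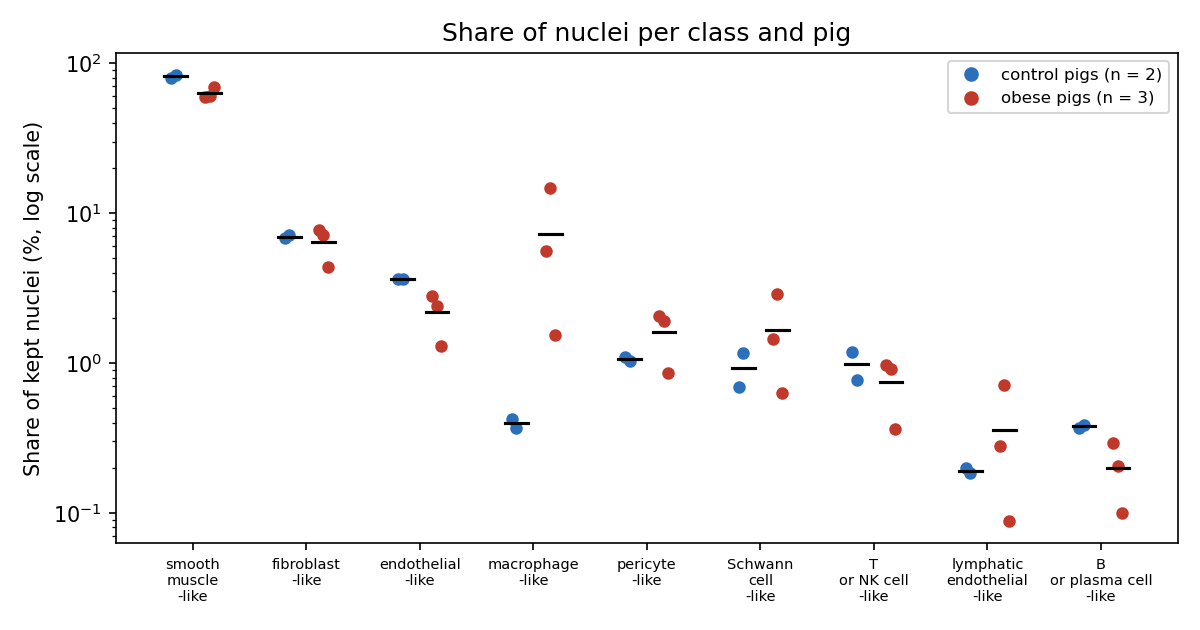
Share of kept nuclei per class (y axis, percent, log scale), with 1 point per pig (obese red, n = 3; control blue, n = 2) and bars at the group mean. The 3 obese pigs lay between 1.53% and 14.8% for macrophage-like nuclei, above both control pigs at 0.368% and 0.425%.

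In smooth muscle-like nuclei, a regulator of sterol genes was lower in obese pigs, and a cholesterol exporter was higher. SREBF2, which encodes the transcription factor SREBP2 that drives sterol genes, fell by 1.62 on the log2 scale (SE 0.20), from 87.2 ± 0.671 CPM (SD, n = 2) to 28.4 ± 2.82 CPM (SD, n = 3). ABCA1, which exports cholesterol and is a target of the LXR receptors, rose by 1.82 (SE 0.23, from 85.4 to 302 CPM). RGS2, a regulator of G protein signalling, rose by 3.24 (SE 0.32), THBS1, which encodes thrombospondin 1, by 3.05 (SE 0.40), and the transcription factor genes KLF2, CEBPD and CEBPB by 2.57, 2.23 and 2.11. ATP8B4 (4.03), CYSLTR2 (3.43), a receptor gene for cysteinyl leukotrienes, PPP1R3C (3.39) and ZFP36L2 (3.24) rose as well. NCAM2 fell as well (-2.76, SE 0.34), and ran from -3.256 to -0.7059 over the alternatives. LAMC3 was named by p alone (-1.98, adjusted p = 0.0528). SPP1, which encodes osteopontin, had 1155 counts in the obese pigs (217, 844 and 94 in replicates 1 to 3) and 3 in the control pigs. The ratio of pooled CPM was 389 (counting interval 133 to 1889). Macrophage markers had a median log2 difference of 2.09 over 10 markers in these nuclei, with a median of 4.2 CPM in obese and 1.28 in control pigs. None passed the threshold, and all obese pigs lay above both control pigs for 5 markers and below them for 1.

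By edgeR, 16 of 17585 genes tested changed in smooth muscle-like nuclei, 12 higher and 4 lower in obese pigs, with adjusted p between 0.0265 for RGS2 and 0.0493 for CEBPB among the named genes. The pigs of the groups did not overlap for any of the 16, and for 5384 of all tested genes, where chance gives 20%. The count was 0, 80 and 85 without obese replicates 1, 2 and 3, and 1 and 2 without control replicates 1 and 2. It was 9 with limma-voom, 553 with the DESeq2 Wald test and 826 with no filter on low counts. It lay between 14 and 42 in the other alternatives.

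**Figure D2:**
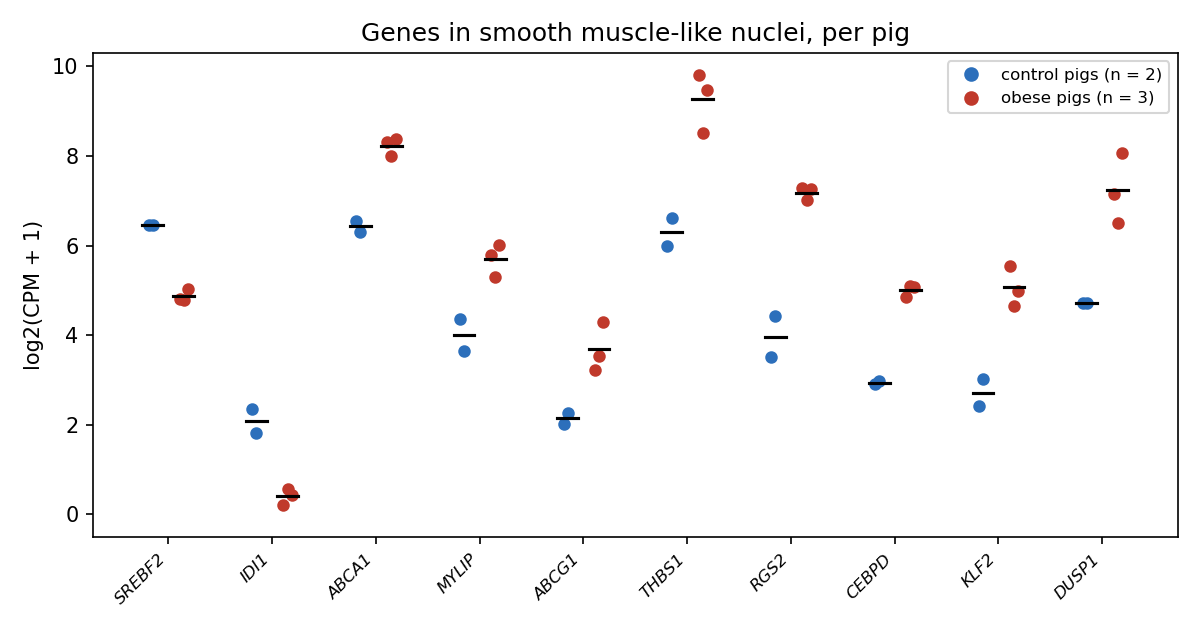
Expression of 10 genes in smooth muscle-like nuclei as log2(CPM + 1) (y axis), with 1 point per pig (obese red, n = 3; control blue, n = 2) and bars at the group mean. SREBF2 and IDI1 lay lower in all 3 obese pigs than in both control pigs, and the other genes higher.

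Among the gene lists in smooth muscle-like nuclei, the list of cholesterol synthesis genes and SREBP2 targets was lower in obese pigs by camera (24 members, median log2 fold change -1.18, adjusted p = 5.28e-15). With an estimated correlation its adjusted p = 0.213, and with fry it was 0.00296. Of 78 list tests over 4 classes, camera called 40, fry 10 and camera with an estimated correlation 0. In this class fry also called the SMC modulation (adjusted p = 0.0172), LXR (0.01025) and hypoxia lists (0.00296). Of the other lists called by camera below, fry called none. Its adjusted p was 0.124 for lipid-laden macrophage, 0.264 for immediate early, 0.225 for complement, 0.118 for NF-kB and 0.231 for interferon-stimulated genes. It was 0.3475 for ribosomal protein and 0.266 for mitochondrial genes. Of the members of the cholesterol synthesis list 3 fell and 0 rose over all genes, and 15 fell and 0 rose adjusted over the list alone, among them IDI1 (-3.22, adjusted p = 0.0528 over all genes). The call held with each pig left out, at medians from -1.31 to -1.15. In the list of LXR targets (12 members, median 0.25, adjusted p = 0.0347, and 0.438 with an estimated correlation) ABCA1 rose over all genes, and 5 members rose and 1 fell adjusted over the list alone. MYLIP had a log2 fold change of 1.74 (adjusted p = 0.0721), APOE 5.54 (0.0971) and SMPDL3A 4.40 (0.0978), beside the values of macrophage markers above. Leaving out obese replicate 3 or control replicate 1 or 2 ended that list's call (adjusted p = 0.0551, 0.142 and 0.0697).

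Lists of stress and of macrophage genes were higher in smooth muscle-like nuclei of obese pigs. For the hypoxia response (20 members, median 0.75, adjusted p = 3.83e-07, and 0.347 with an estimated correlation) 0 members passed over all genes and 9 were higher adjusted over the list alone. They include VEGFA, a growth factor for vessels, at 1.87 and LDHA at 1.59. Immediate early and heat shock genes, which respond to tissue handling, had a median of 1.15 over 19 members (adjusted p = 1.37e-05, and 0.534 with an estimated correlation). Of these, 0 passed the threshold over all genes and 7 were higher adjusted over the list alone, including DUSP1 (2.73) and ZFP36 (2.65). Without control replicate 1 that call ended (median 0.72, adjusted p = 0.226). The lipid-laden macrophage list had a median of 2.17 over 19 members (adjusted p = 2.28e-08, and 0.438 with an estimated correlation). SPP1 passed the threshold over all genes, and 11 members were higher adjusted over the list alone, including LGALS3 (3.85) and ABCG1 (1.87), beside the same marker values. SMC modulation genes had a median of 0.82 over 16 members (adjusted p = 0.00042, and 0.362 with an estimated correlation). Of these, 2 were higher over all genes and 5 adjusted over the list alone, VCAM1 at 2.21 among them. SPP1 and LGALS3 belong to this list and to the lipid-laden macrophage list, so the same marker values apply. ABCG1 and APOE belong to the LXR list and to the lipid-laden macrophage list.

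Complement genes (median 0.95, 11 members, adjusted p = 0.00267, and 0.478 with an estimated correlation) had 0 members past the threshold over all genes and 4 higher adjusted over the list alone, including C3 (3.07). NF-kB targets and adhesion molecules (median 0.57, adjusted p = 0.0132, and 0.438 with an estimated correlation) had 0 and 1 in the same order, and interferon-stimulated genes (median 0.30, adjusted p = 0.0331, and 0.543) 0 and 0. The counts were 0 and 0 also for ribosomal protein genes (median 0.25, adjusted p = 0.00821, and 0.645) and mitochondrial genes (median 0.57, adjusted p = 0.0161, and 0.534). Each of these last 4 calls ended without obese replicate 3 (adjusted p = 0.0958, 0.0882, 0.057 and 0.10). Interferon-stimulated and ribosomal protein genes also lost the call without obese replicate 2 (0.12 and 0.0881), and both of them and the mitochondrial genes without control replicate 2 (0.454, 0.298 and 0.0541). Mitochondrial genes lost it without obese replicate 1 too (0.057). SMC contractile genes were not called (19 members, median 0.03, adjusted p = 0.743). Adjusted over that list alone, 2 members were higher, ACTG2 (1.34) and PLN (1.39), and 1 was lower, MYL9 (-1.11), and none passed over all genes. Osteochondrogenic (median -0.11), interstitial matrix (-0.21), basement membrane (-0.25), fatty acid oxidation (-0.29), fatty acid uptake (-0.08), resident macrophage (0.24), TGF-beta (0.10), unfolded protein response (0.21), oxidative phosphorylation (-0.03) and insulin (0.17) lists were not called, at adjusted p from 0.0769 to 0.961. None of their members passed over all genes. Adjusted over the list alone, ANGPTL4 (2.96) was higher in fatty acid uptake, TGFB3 (2.01) in the TGF-beta list, and F13A1 (4.42) and CD163 (4.18) in the resident macrophage list, where MERTK (-1.14) was lower. Within the fatty acid oxidation list PDK4, a kinase that holds back glucose oxidation, had 2.47 and ACAA2 -1.69, with 1 member higher and 3 lower adjusted over the list alone. The insulin and glucose list had 4 members higher adjusted over the list alone, including TXNIP (1.32) and HK2 (1.62). For oxidative phosphorylation the mean was 0.00896 and the test pointed up, against the sign of the median. The mean of fatty acid uptake was 0.303, against the sign of its median and its test.

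In fibroblast-like nuclei most of the changed genes were higher in obese pigs. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 3.19 on the log2 scale (SE 0.41), PTGS2, the inducible prostaglandin synthase, by 2.50 (SE 0.40), and ATF3 and FOSL2, stress-responsive transcription factor genes, by 3.25 (SE 0.47) and 2.83 (SE 0.34). UAP1 (2.71), ZFP36 (2.58) and ZFP36L2 (2.41) also rose. SPP1 had 139 counts in obese pigs (31, 99 and 9 in replicates 1 to 3) and 0 in control pigs. It was at least 34.6-fold higher, with free RNA from macrophages not subtracted. CAVIN3, a component of caveolae, fell by 3.21 (SE 0.47), PI16, a marker of adventitial fibroblasts, by 1.90 (SE 0.30, from 135 to 35.6 CPM) and GXYLT2 by 1.38 (SE 0.22). SERTAD4 (-1.86, adjusted p = 0.0513) and TEF (-1.74, adjusted p = 0.0529) were named by p alone. In edgeR 31 of 9145 genes tested changed, 28 higher and 3 lower, with adjusted p from 0.0183 for FOSL2 to 0.0425 for SPP1 among the named genes. The count was 4, 65 and 141 without obese replicates 1, 2 and 3, and 0 without control replicate 1 or 2. It was 138 with the DESeq2 Wald test, 391 with no filter, 11 in cluster 7 alone and 0 in cluster 13 alone, single clusters chosen after seeing the data.

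Immediate early and heat shock genes were the list with the smallest p in fibroblast-like nuclei (18 members, median 1.76, adjusted p = 3.18e-15, and 0.362 with an estimated correlation). All 18 had positive values, 2 rose over all genes and 16 adjusted over the list alone, with EGR1 at 1.71 and DUSP1 at 1.66, and the call held with each pig left out. Fry called no list in this class, and its adjusted p was 0.054 for immediate early and heat shock genes. SMC modulation genes (median 0.46, adjusted p = 0.0017, and 0.438 with an estimated correlation) had 3 members higher over all genes, THBS1 (2.31), KLF4 (2.07) and SPP1, and 5 adjusted over the list alone. SPP1 is also a member of the lipid-laden macrophage list. The hypoxia response (median 0.39, adjusted p = 0.00821, and 0.438 with an estimated correlation) had 1 and 4, with HIF1A at 1.38. Lipid-laden macrophage genes (median 1.37, adjusted p = 0.00137, and 0.478 with an estimated correlation) had 1 and 6, with CTSD at 2.42, and complement genes (median 1.47, adjusted p = 0.0159, and 0.538) 0 and 3, with C3 at a ratio of pooled CPM of 34.2 (11.4 to 168). NF-kB targets (median 0.66, adjusted p = 0.0421, and 0.438) had 0 and 2, with BIRC3 at 1.52, and the unfolded protein response (median 0.47, adjusted p = 0.0165, and 0.534) 0 and 1, HSPA5 (2.23). Fatty acid oxidation genes were lower (median -0.40, adjusted p = 0.0298, and 0.478 with an estimated correlation), with 0 members past the threshold over all genes and 4 lower and 1 higher adjusted over the list alone, among them PPARA (-1.42) and CPT2 (-1.54). Lipid-laden macrophage genes lost the call without obese replicate 2 (adjusted p = 0.097), and complement genes without obese replicate 1 or control replicate 2 (0.063 and 0.0692). So did the unfolded protein response without control replicate 2 (0.0622) and fatty acid oxidation without obese replicate 3 or control replicate 1 (0.0882 and 0.185). The sterol list was not called in fibroblast-like nuclei (13 members, median -0.26, adjusted p = 0.175), where SREBF2 had -0.36, with 0 members past the threshold over all genes and 0 adjusted over the list alone. The SMC contractile (median 0.03), osteochondrogenic (-0.01), interstitial matrix (-0.29), basement membrane (-0.03), LXR (0.21), fatty acid uptake (0.46), interferon (-0.22), TGF-beta (0.14), oxidative phosphorylation (-0.11), insulin (0.25) and ribosomal protein (0.29) lists were not called, at adjusted p from 0.0775 to 0.982. The test of the osteochondrogenic list pointed up, against the sign of its median. Adjusted over the list alone, COL4A1 (1.21) was higher and COL4A4 (-1.64) and COL15A1 (-1.03) lower in the basement membrane list, and 4 insulin genes were higher, including HK2 (2.69). ANGPTL4 was the member past the threshold in the fatty acid uptake list.

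Endothelial-like nuclei had the most called genes, and most of these were higher in obese pigs. IL6, a cytokine gene, rose by 4.28 on the log2 scale (SE 0.65), from 6.34 ± 1.60 CPM (SD, n = 2) to 124 ± 77.5 CPM (SD, n = 3). PTGS2 rose by 4.27 (SE 0.94), DUSP5, a phosphatase that acts on ERK, by 4.85 (SE 0.55), and the phosphodiesterase genes PDE4B and PDE1C by 4.50 (SE 0.69) and 4.37 (SE 1.11). RNF122 (4.92), TAFA5 (4.61), RELL1 (4.26) and TRIB1 (4.15) also rose. SPP1 had 78 counts in obese pigs (16, 59 and 3 in replicates 1 to 3) and 0 in control pigs. It was at least 65.6-fold higher, also without subtraction of free RNA. ASS1, an enzyme of arginine synthesis, fell by 3.82 (SE 0.47), LTBP2, a microfibril protein gene, by 3.07 (SE 0.36), MFAP5, another, by 3.23 (SE 0.53), and NTN1, a guidance cue gene, by 2.95 (SE 0.59). DPP10 (-4.57), PROSER2 (-3.90), GRID1 (-3.65, SE 0.33) and PLEKHA6 (-3.30) fell as well. SMTNL2, with 1 count in the obese pigs, was 117-fold lower (counting interval 20.9 to 4650), and MYOZ3, with 2 counts, 15.1-fold lower (4.05 to 127). In edgeR 554 of 6603 genes tested changed, 388 higher and 166 lower, with adjusted p from 0.00314 for GRID1 to 0.0405 for PDE1C among the named genes. The count was 246 and 176 without control replicates 1 and 2 and 1113 with no filter on low counts. It was 107 in cluster 15 alone and 0 in cluster 17 alone, alternatives chosen after seeing the data. Cluster 15 held 0.603% of nuclei in obese and 2.66% in control pigs, and cluster 17 held 1.57% and 0.959%, so the class had a different make-up in each group. Depth per nucleus was lower in obese pigs, with 534990, 498156 and 333625 UMIs in 200, 224 and 118 nuclei of obese replicates 1 to 3. Control replicates 1 and 2 had 2530591 and 1230410 UMIs in 401 and 197 nuclei. Whether depth gives part of the called genes was not tested. Markers of venous endothelium had a median log2 difference of 2.37 in the class (4 of 6 past the threshold), those of capillary endothelium 1.34 (1 of 4) and smooth muscle markers 0.979 (1 of 8). Fibroblast markers had a median of -0.564 (1 of 5), with all obese pigs below both control pigs for 2 markers and above them for 1. These groups of markers were not tested as lists.

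Immediate early and heat shock genes were higher in endothelial-like nuclei of obese pigs (17 members, median 1.57, adjusted p = 8.27e-07, and 0.438 with an estimated correlation). Of these, 10 were higher over all genes and 12 adjusted over the list alone, including the immediate early genes ATF3 (3.37), EGR1 (2.80), FOS (2.66) and FOSB (2.86), and 3 had negative values. HSP70.2, a heat shock gene, had -2.52 (adjusted p = 0.0953), against the direction of the list. It was not counted in the list, whose members HSPA1A and HSPA1B were not matched by name. Basement membrane genes (median 0.59, adjusted p = 0.0159, and 0.534 with an estimated correlation) had 5 higher over all genes and 5 adjusted over the list alone, with the collagen IV genes COL4A1 (2.49, SE 0.30) and COL4A2 (2.40), NID1 (3.34) and LAMA3 (2.20). LAMA3 had the opposite sign in cluster 17 alone. Lipid-laden macrophage genes (median 1.67, adjusted p = 2.55e-05, and 0.362 with an estimated correlation) had 5 and 7, among them the lysosomal protease genes CTSB (3.10) and CTSD (3.46). Hypoxia genes (median 1.47, adjusted p = 0.00129, and 0.438) had 5 and 8, with P4HA1 (2.11) and EGLN3 (2.72). NF-kB targets and adhesion molecules (median 1.10, adjusted p = 0.00516, and 0.539) had 3 higher over all genes, including VCAM1 (3.35), which binds leukocytes, and BIRC3 (2.88), and 5 higher and 1 lower adjusted over the list alone. VCAM1 is also on the fixed list of venous endothelial markers, which had a median of 2.37 in the class. No list was tested in single clusters. Interferon-stimulated genes (median 1.14, adjusted p = 0.000312, and 0.438) had 1 and 2, with MX2 at 3.70 and IFI44 at 1.61. These 6 camera calls held with each pig left out. Fry called the lipid-laden macrophage and hypoxia lists (adjusted p = 0.0316 and 0.0473). It did not call immediate early (0.0651), basement membrane (0.0862), NF-kB (0.239) or interferon-stimulated genes (0.0768).

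LXR targets (median 1.70, adjusted p = 0.0159, and 0.438 with an estimated correlation) had 2 higher over all genes, ABCA1 (2.17) and ABCG1 (2.14), and 3 adjusted over the list alone. ABCG1 is also a member of the lipid-laden macrophage list. Fatty acid uptake and storage (median 1.24, adjusted p = 0.0298, and 0.554) had 1 higher over all genes, ANGPTL4 (3.76), and 2 higher and 1 lower adjusted over the list alone. Fatty acid oxidation was lower (median -0.68, adjusted p = 0.0421, and 0.478), with CPT1A (-1.51) the 1 member past both adjustments. SMC contractile genes (median 0.59, adjusted p = 0.0298, and 0.478) had MYOCD (1.55) past the threshold over all genes and 4 adjusted over the list alone, beside the positive median of smooth muscle markers above. Ribosomal protein genes (median 0.56, adjusted p = 0.0201, and 0.557) had 0 and 0. Leaving out obese replicate 3 ended the LXR call (adjusted p = 0.0503), obese replicate 2 or 3 or control replicate 2 that of fatty acid uptake (0.064, 0.0987 and 0.0697), and obese replicate 1 or control replicate 1 that of fatty acid oxidation (0.0707 and 0.268). Obese replicate 2 or 3 or control replicate 2 ended that of contractile genes (0.0935, 0.0608 and 0.144), and control replicate 2 that of ribosomal protein genes (0.0664). Members of the TGF-beta and endothelial-mesenchymal list went both ways, with LTBP2, TGFB2 (-2.33) and CCN2 (-1.80) lower and TGFBR3 (1.76) higher over all genes, and 3 higher and 5 lower adjusted over the list alone. That list was not called (adjusted p = 0.743), and its median of 0.19 had the opposite sign to its mean of -0.199 and its test. In cluster 17 alone TGFB2 and TGFBR3 had the opposite sign, and LTBP2 ran from -3.32 to -0.488 over the alternatives. ELN, the elastin gene, fell by 1.59 (SE 0.28) and COL12A1 rose by 1.51 (SE 0.35) in the interstitial matrix list, which was not called (adjusted p = 0.66), with the same 2 members past the threshold adjusted over the list alone. INSR (2.02) rose in the insulin list, also not called (adjusted p = 0.367), with 1 member higher over all genes and 3 adjusted over the list alone. SMC modulation (median 0.22, 3 members higher by both adjustments), unfolded protein response (0.23) and oxidative phosphorylation (-0.43) lists were not called by camera either (adjusted p = 0.232, 0.617 and 0.0911). Fry called SMC modulation (adjusted p = 0.0179) and no other list of this paragraph.

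In macrophage-like nuclei of obese pigs 8 genes were called higher, and MRC1 and COLEC12 were called lower. SPP1 had 7113 counts in obese and 0 in control pigs. By the mean CPM of the obese pigs it was at least 37.7-fold higher, MCOLN3, a lysosomal channel gene, at least 34.7-fold and SEMA3C at least 19.3-fold. FRMD5 was 141-fold higher by pooled CPM (counting interval 25.3 to 5565), MYO10 90.3-fold (16.2 to 3567), ANKH, which carries pyrophosphate precursors out of cells, 89.2-fold (16.0 to 3523), ENPP1, which makes pyrophosphate, 71.3-fold (19.7 to 589) and CTSD, a lysosomal protease gene, 29.8-fold (8.24 to 246). MRC1, the mannose receptor gene of resident macrophages, fell by 4.90 on the log2 scale (SE 0.47), from 1143 ± 333 CPM (SD, n = 2) to 36.7 ± 12.9 CPM (SD, n = 3), and COLEC12, a scavenger receptor gene, fell by 3.23 (SE 0.42). DCDC2 (-4.83), FRMPD4 (-2.69) and KCNB2 (-3.00) were named by p alone (adjusted p = 0.102 each). In edgeR 10 of 5662 genes tested changed, 8 higher and 2 lower, with adjusted p from 0.0129 for MRC1 to 0.045 for FRMD5. The control pigs gave 47 and 20 macrophage-like nuclei with 58780 and 41593 UMIs. The count was 42, 26 and 3 without obese replicates 1, 2 and 3, 0 without control replicate 1 or 2, 1 with limma-voom, 111 with the DESeq2 Wald test and 246 with no filter. It was also 20 with a stricter filter on low counts, 41 with centring per library and 18 in cluster 9 alone, an alternative chosen after seeing the data. The latter leaves out cluster 12, of whose 765 nuclei 723 came from obese replicate 2 and 0 from control pigs. In cluster 9 alone the fitted log2 fold changes of FRMD5, MYO10, ANKH and ENPP1 were 6.42, 5.85, 6.23 and 5.55, against 6.92, 6.26, 6.45 and 6.05 in the class, and that of MRC1 was -3.43 (adjusted p = 0.0939). Obese replicate 2 weighs most in the pooled ratios, with 6399133 UMIs in the class against 1262145 and 317474 in obese replicates 1 and 3.

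**Figure D3:**
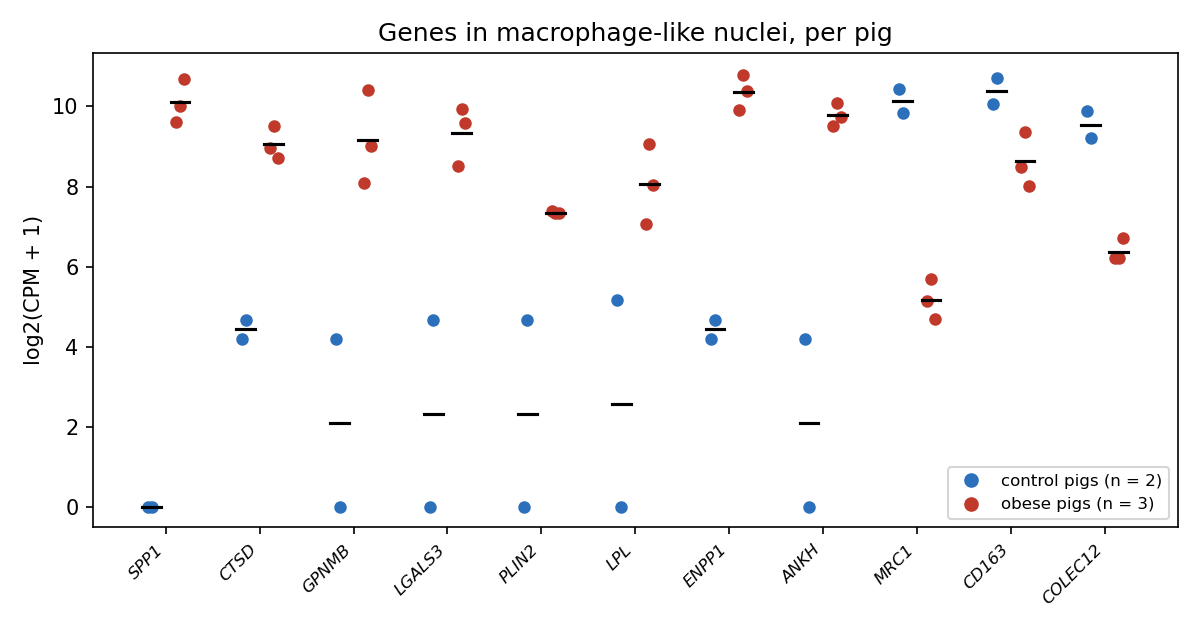
Expression of 11 genes in macrophage-like nuclei as log2(CPM + 1) (y axis), with 1 point per pig (obese red, n = 3; control blue, n = 2) and bars at the group mean. MRC1, CD163 and COLEC12 lay lower in all 3 obese pigs, and SPP1 was at 0 in both control pigs.

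The lipid-laden macrophage list was higher in macrophage-like nuclei of obese pigs (17 members, adjusted p = 2.88e-10, and 0.438 with an estimated correlation), at a median log2 fold change of 3.95, or 2.60 with members at 0 in control pigs set to their bound. All 17 members had positive values, 2 rose over all genes and 13 adjusted over the list alone, and the call held with each pig left out. Fry called this list (adjusted p = 0.0179), LXR targets (0.0253) and hypoxia genes (0.0287), and no other list in this class. LGALS3 was 76.5-fold higher by pooled CPM (13.7 to 3023, adjusted p = 0.0682) and GPNMB 101-fold (18.1 to 3978, adjusted p = 0.119). Without cluster 12 the fitted log2 fold changes were 5.45 for LGALS3, 5.44 for GPNMB and 3.12 for LPL, against 6.08, 6.14 and 3.95 in the class. In the list of fatty acid uptake and storage (median 1.64, adjusted p = 0.0333, and 0.534 with an estimated correlation) 0 members passed over all genes and 4 rose adjusted over the list alone, among them PLIN2, which coats lipid droplets, at 14.2-fold (2.54 to 562) and LPL, lipoprotein lipase, at 20-fold (5.54 to 166). LXR targets (median 1.37, or 0.97 with members at their bound, adjusted p = 0.021, and 0.478) had 0 and 2, with SMPDL3A at least 19.1-fold and APOE at least 4.34-fold higher. PLIN2, LPL and APOE are also members of the lipid-laden macrophage list, so these calls are not fully separate. Hypoxia genes (median 1.30, or 0.75 at the bound, adjusted p = 0.0131, and 0.438) had 0 and 1, NDRG1 at 14.2-fold (4.85 to 68.8). Resident macrophage genes were lower (median -1.07, adjusted p = 0.041, and 0.438), with MRC1 lower over all genes and MRC1 and CD163 (-1.67) adjusted over the list alone. MHC class II genes were also lower (5 members, median -1.32, adjusted p = 0.00866, and 0.438), with 0 and 0 members past the threshold and CD74 at -0.90.

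SMC contractile genes were lower in macrophage-like nuclei (median -0.75, adjusted p = 0.00244, and 0.599 with an estimated correlation), as were interstitial matrix genes (-0.71, adjusted p = 0.0228, and 0.634), basement membrane genes (-0.67, adjusted p = 0.0336, and 0.645) and ribosomal protein genes (-0.75, adjusted p = 0.021, and 0.534), each with 0 members past the threshold over all genes and 0 adjusted over the list alone. Smooth muscle markers had a median log2 difference of -0.755 in this class over 8 markers. Leaving out control replicate 1 ended most of the calls in this class, and so did leaving out control replicate 2. Without it adjusted p = 0.144 for contractile, 0.144 for interstitial matrix and 0.849 for basement membrane genes, 0.0664 for ribosomal protein, 0.448 for fatty acid uptake, 0.112 for LXR, 0.246 for resident macrophage and 0.0697 for MHC class II genes. Without control replicate 1, adjusted p = 0.226 for LXR, 0.0833 for MHC class II, 0.0507 for interstitial matrix, 0.23 for basement membrane, 0.278 for hypoxia, 0.0674 for resident macrophage and 0.293 for ribosomal protein genes. Leaving out obese replicate 1 ended the hypoxia and resident macrophage calls (0.147 and 0.386), obese replicate 2 the contractile, interstitial matrix and basement membrane calls (0.236, 0.233 and 0.171), and obese replicate 3 the hypoxia and fatty acid uptake calls (0.10 and 0.121). The SMC modulation (median 0.10), fatty acid oxidation (-0.35), NF-kB (0.19), interferon (0.49), TGF-beta (0.69), unfolded protein response (-0.23), oxidative phosphorylation (0.00886), insulin (0.22) and immediate early (0.36) lists were not called, at adjusted p from 0.232 to 0.982. The test of the immediate early list pointed down, against the sign of its median. Fatty acid oxidation and the unfolded protein response had means of 0.527 and 0.246, against the sign of their medians and tests. Adjusted over the list alone, 2 members were higher in the SMC modulation list, where SPP1 also passed over all genes, and 2 in the interferon list, and 1 each in the NF-kB and insulin lists.

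**Figure D4:**
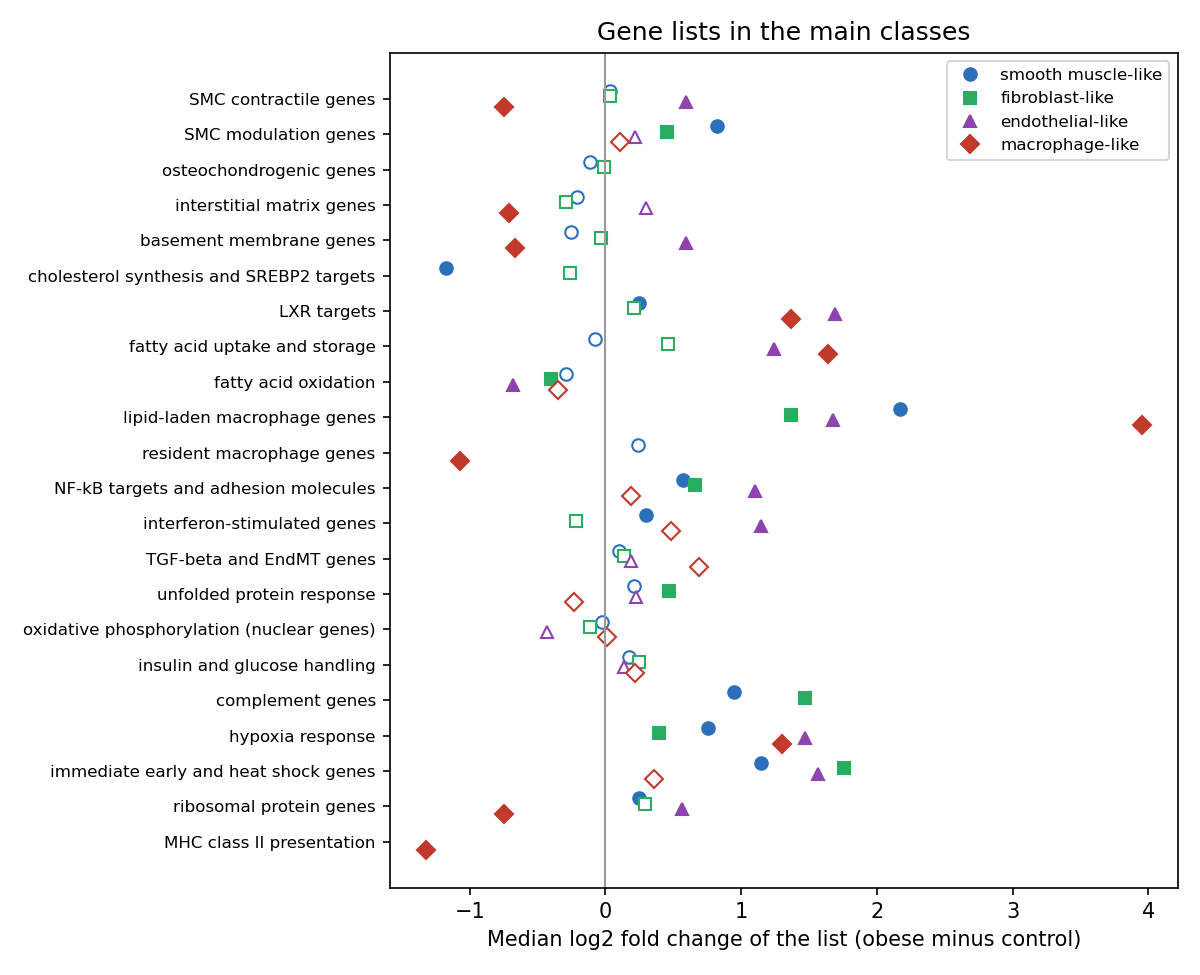
Median log2 fold change (x axis, obese minus control) of the gene lists except mitochondrial genes (y axis) in 4 classes, given by colour and shape. A point is drawn where a list had at least 5 tested members in the class. It is filled where camera at the preset correlation gave an adjusted p under 0.05. Lipid-laden macrophage genes reached 3.95 in macrophage-like nuclei and the sterol list -1.18 in smooth muscle-like nuclei.

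Whether the diet effect itself differed between classes was tested as an interaction. Between endothelial-like and smooth muscle-like nuclei 703 of 16727 genes differed by edgeR, 336 with a more positive and 367 with a more negative effect in endothelial-like nuclei. With DESeq2 size factors 739 differed, 486 more positive and 253 more negative, and with cluster 15 alone 43 and 136. The heat shock gene HSP70.2, named from a table of identifiers, had a difference of -4.82 (SE 0.40). It had 2264, 9878 and 10400 counts in smooth muscle-like nuclei of obese pigs and 238 and 11833 in those of control pigs, against 47, 325 and 55 and 1008 and 3835 in endothelial-like nuclei. HES4, CD69, GRIN2B, KCNK13, SLC38A3, TEKT1, NUDCD2, CISH and SMTNL2 were named by the same rule. Each had at most 3 counts in a group of endothelial-like nuclei, and no fold is given for them. The count was 213 with limma-voom, 367 and 221 without control replicates 1 and 2, and 179 and 33 with cluster 15 and cluster 17 alone. Between fibroblast-like and smooth muscle-like nuclei 0 of 16347 genes differed by edgeR, with 1068 at an unadjusted p under 0.05 and 0 by limma-voom. That count was 29, 17 and 37 without obese replicates 1, 2 and 3, 2 without control replicate 2, 11 with DESeq2 size factors and 211 with no filter.

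Schwann cell-like, T or NK cell-like and pericyte-like nuclei had 0 called genes by edgeR, and the T or NK cell-like count was 30 without control replicate 2. At an unadjusted p under 0.05 there were 326 of 3587 genes in Schwann cell-like, 395 of 3629 in T or NK cell-like and 544 of 5137 in pericyte-like nuclei. The DESeq2 Wald test called 8, 22 and 27 genes in these classes and limma-voom 3, 0 and 0. In T or NK cell-like nuclei smooth muscle markers had a median log2 difference of 0.676 over 7 markers. Their median was 409 CPM in obese and 265 in control pigs. None passed the threshold, and carry-over of smooth muscle RNA was not tested there. The genes of smallest p, given as values, were PDK4 (3.46), NFKBIZ (2.76), CTNNA3 (1.77), UGCG (2.68), NTN4 (-2.19), MEOX1 (-2.90), IFNGR2 (-1.84), JAG1 (-2.02) and TMEM132C (-2.60) in Schwann cell-like nuclei, at adjusted p from 0.115 to 0.19, with ANKS1B at a ratio of 32.3 (8.81 to 269). In T or NK cell-like nuclei they were NOX4 (1.99), SPSB1 (2.53), THBS1 (3.73), CERS6 (2.58), SYK (-3.39), TESK2 (-2.01), CLIP4 (-3.35), SUSD1 (-2.14) and RAP1GAP2 (-1.75), at adjusted p from 0.0859 to 0.116, with ARMC9 at a ratio of 16.0 (5.11 to 80.6). In pericyte-like nuclei they were HSPH1 (2.47), RUNX1 (2.73), MAMLD1 (2.99), ANGPTL4 (3.02), PRR16 (3.52), TTLL7 (-2.14), MICU3 (-1.93), MAMDC2 (-1.91), GPC3 (-1.88) and SLC22A4 (-2.48), each at adjusted p = 0.173, and PRR16 had -0.24 at a Leiden resolution of 0.5. Camera was also run in these smaller classes, outside the adjustment over the main ones. Immediate early and heat shock genes had medians of 1.24 in Schwann cell-like, 0.874 in T or NK cell-like and 0.689 in pericyte-like nuclei. Its unadjusted p was 4.70e-06, 0.00261 and 0.000203, and 0.128, 0.302 and 0.218 with an estimated correlation. Hypoxia genes had medians of 1.14, 1.21 and 1.00 in the same order. Handling and diet cannot be told apart for these lists. Over all nuclei together, which mixes expression and composition, GRIP1 (-3.26, SE 0.28, adjusted p = 0.0478) was the 1 gene of 20052 that changed, with 2825 at an unadjusted p under 0.05. HK2 (3.69), ABCA1 (1.93), SPP1 (9.44), ZFP36L2 (2.64), RGS2 (3.02), MALL (-2.82), ANO4 (-2.50), SMTNL2 (-3.96) and KIF26A (-3.05) followed at adjusted p = 0.0725. The whole-library count was 798 with the DESeq2 Wald test, 560 with no filter and 1 with limma-voom. It was 0, 210 and 351 without obese replicates 1, 2 and 3, and 0 without control replicate 1 or 2.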

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

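The tests of endothelial clusters 15 and 17 below were chosen after the result was seen and replaced a single test of both clusters that had left the question open, and the look at kidney tubule genes, the addition of clusters 3 and 18 and the removal of cluster 11 were also chosen after seeing the data.

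The diet effect differed between endothelial-like and smooth muscle-like nuclei for 703 genes by the interaction test, a difference between the 2 classes under the same contrast. Many of its p-values are very small for 5 pigs with 3 residual degrees of freedom. The test pools the spread over genes, and the cause of the small p-values was not tested. With limma-voom 213 genes differed. The difference in diet effect of HSP70.2, a heat shock gene, was -4.82 on the log2 scale. It lay between -6.74 and -2.95 with each pig left out, at -3.95 with limma-voom, at -5.29 with endothelial cluster 15 alone, and at -0.58 with cluster 17 alone, where it was no longer past the threshold. The control pigs themselves were far apart, with 238 and 11833 counts of HSP70.2 in smooth muscle-like nuclei.

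The endothelial-like nuclei came from clusters 15 and 17 in unequal parts, so a different mix of the clusters in obese and control pigs was weighed as an explanation of the called genes of that class. In cluster 15 alone 107 genes were called, 93 of them also called in the class. For those 93 genes this argues against the mix as the whole cause. The median log2 fold change of 390 of the 554 called genes in cluster 15, in the direction of the class, was 1.51 against 2.03 in the class. That median cannot decide the question, since the called genes were chosen from nearly the same control data, which favours a high value. Cluster 15 held 2221638 of 2530591 and 1151580 of 1230410 UMIs of the class in control replicates 1 and 2. Its nuclei also held fewer UMIs each in obese pigs, and depth was not tested. In cluster 17 alone the median of 429 called genes was 0.919 and 0 genes were called by edgeR, so for that cluster the mix and a change within cells cannot be told apart at this depth. Cluster 15 was mostly from control pigs and cluster 17 mostly from obese pigs, and a part of each gene's difference in the class may come from the mix. Differences in diet, collection, handling or depth per nucleus between the groups stay open, and no test separates them.

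Cluster 3, which no comparison of genes uses by itself, held more nuclei in obese than in control pigs, by 12.1 percentage points. Its share was 13%, 7.97% and 18.3% in the obese pigs and 0.343% and 1.58% in the control pigs. Its genes of highest fold over other clusters, named after their values were seen, were GPRC5A, INHBA, NFATC2, EMP1, FLNC and SERPINE2. When clusters 3 and 18 were added to the smooth muscle-like nuclei, 36 genes were called in place of 16.

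Cluster 11, also unnamed, held 2.86 percentage points more of the nuclei in obese pigs, with 6.62%, 0.463% and 2.90% in the obese and 0.497% and 0.441% in the control pigs, so obese replicate 2 lay with the control pigs. Genes of the kidney tubule were high in it, with CUBN at 553 CPM against 27.8 in other nuclei, PCK1 at 146 against 0.105, and G6PC1 at 104 against 0.274. The list of 12 such genes was written before their levels were compared, though CUBN, PCK1 and PKHD1 had been seen among the leading genes of the cluster. The kidney tubule list was also part of the rule by which names were withheld. All 12 were higher in cluster 11 than in other nuclei. Nuclei or RNA of kidney may be a candidate source, and the sort on a DNA stain would not remove such nuclei. In the test over all nuclei without cluster 11, the count of changed genes was 2 in place of 1.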

How the results depend on the processing

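Single clusters of a class, the addition of clusters 3 and 18, nuclei of at least 2000 UMIs and all nuclei without cluster 11 were chosen after seeing the data, and the other alternatives before. The causes of the changes in this part were not tested, apart from the loss of pigs, genes or nuclei that an alternative brings by itself.

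Of 357 single genes and list medians that the text could name, alternatives gave the same direction and side of the threshold 4263 times, the same direction without the call 449 times, the same direction with a new call 415 times and the opposite direction 122 times. Each named gene called within a class kept its direction in every alternative run for it, apart from list members given below for cluster 17. In smooth muscle-like nuclei SREBF2 kept its call in 15 of 18 alternatives (-1.70 to -1.51) and ABCA1 in 15 of 18, while NCAM2 kept it in 13 of 17 (-3.26 to -0.71). MRC1 kept it in 13 of 16 in macrophage-like nuclei (-5.29 to -3.43). Ranges were also wide for LTBP2 (-3.32 to -0.49) and TRIB1 (1.29 to 4.79) in endothelial-like nuclei and for UAP1 (0.59 to 2.95) and PTGS2 (0.98 to 2.76) in fibroblast-like nuclei. In macrophage-like nuclei the lowest values were 5.98 for FRMD5, 5.06 for MYO10 and 4.81 for ANKH.

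The number of genes changed in smooth muscle-like nuclei (16) was 553 with the DESeq2 Wald test, 9 with limma-voom, 826 with no filter on low counts, 41 with no doublet removal, 30 with a stricter filter on nuclei, 41 when centred per library, 37 with the ambient filter, 36 with low-marker clusters added, 32 in nuclei of at least 2000 UMIs, and 0 to 85 with each pig left out. In fibroblast-like nuclei (31) it was 138 with the DESeq2 Wald test, 391 with no filter, 11 in cluster 7 alone, 0 in cluster 13 alone and 0 to 141 with each pig left out. In endothelial-like nuclei (554) it was 1113 with no filter, 107 in cluster 15 alone, 0 in cluster 17 alone and 176 to 513 with each pig left out. In macrophage-like nuclei (10) it was 111 with the DESeq2 Wald test, 1 with limma-voom, 246 with no filter, 20 with a stricter filter on low counts, 41 when centred per library, 18 in cluster 9 alone and 0 to 42 with each pig left out. The stricter filter on nuclei gave no macrophage-like value, since control replicate 2 kept too few nuclei, and the ambient filter does not apply to all nuclei together.

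For Schwann cell-like nuclei (0 by edgeR, 326 at an unadjusted p under 0.05) the count was 8 with the DESeq2 Wald test, 3 with limma-voom, 50 with no filter, 16 with a stricter filter on low counts, 2 with no doublet removal and 0 to 4 with each pig left out. For T or NK cell-like nuclei (0 by edgeR, 395 at an unadjusted p under 0.05, 0 with limma-voom) it was 22 with the DESeq2 Wald test, 70 with no filter, 30 with a stricter filter on low counts and 0 to 30 with each pig left out. For pericyte-like nuclei (0 by edgeR, 544 at an unadjusted p under 0.05, 0 with limma-voom) it was 27 with the DESeq2 Wald test, 77 with no filter and 1 at a Leiden resolution of 0.5. Over all nuclei (1) it was 798 with the DESeq2 Wald test, 560 with no filter, 0 with a stricter filter on low counts, 0 with a stricter filter on nuclei, 2 without cluster 11 and 0 to 351 with each pig left out. Genes whose diet effect differed between fibroblast-like and smooth muscle-like nuclei (0) numbered 11 with DESeq2 size factors, 211 with no filter and 0 to 37 with each pig left out. Between endothelial-like and smooth muscle-like nuclei (703) they numbered 213 with limma-voom, 179 with cluster 15 alone, 33 with cluster 17 alone and 221 to 601 with each pig left out. Of the 78 list tests, 40 were called, against 0 with an estimated correlation, 10 with fry and 26 to 35 with each pig left out.

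With the replicate number as a replicate block, the count was 42 in smooth muscle-like, 20 in fibroblast-like, 520 in endothelial-like, 48 in macrophage-like and 12 in Schwann cell-like nuclei, 406 over all nuclei, and 38 for the lists. Whether pigs of the same number shared a batch is not given in the sources used here, and only replicates 1 and 2 are in both groups. Obese replicate 3 was alone in its block, so it added nothing to the blocked diet effect. Fewer residual degrees of freedom were left as well. These counts therefore mix the block with the loss of that pig. Its removal without a block gave 85 in smooth muscle-like nuclei and 351 over all nuclei. After removal of the group means, the profiles of replicates 1 and of replicates 2 had correlations of 0.241 and 0.0127 in smooth muscle-like, 0.0943 and -0.159 in fibroblast-like, 0.0829 and 0.0029 in endothelial-like and -0.183 and -0.159 in macrophage-like nuclei. With 2 control pigs, their profiles are exact opposites after that removal, so the 2 values of a class are not separate evidence. The block turned the medians of SMC contractile genes in smooth muscle-like (-0.18) and fibroblast-like nuclei (-0.0227), oxidative phosphorylation in smooth muscle-like (0.0531), the TGF-beta list in endothelial-like (-0.12), and SMC modulation (-0.40), NF-kB targets (-0.26) and immediate early genes (-0.0938) in macrophage-like nuclei. It also turned SOX5 (0.14) and COL4A2 (-0.0899) in smooth muscle-like, TRPS1 (-0.14) and SOX5 (0.0802) in fibroblast-like and FN1 (-0.64) in macrophage-like nuclei.

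The difference in share changed sign with pigs left out for fibroblast-like nuclei (-1.24 to 0.414 percentage points) and lymphatic endothelial-like nuclei (-0.00708 to 0.304). An edgeR test of nuclei counts called the share of macrophage-like nuclei (log2 fold change 4.19, adjusted p = 0.000446) and of smooth muscle-like nuclei (-0.37, adjusted p = 0.0363), where the exact test cannot call any. It also called the share of unnamed nuclei (2.11, adjusted p = 0.00112). With clusters 3 and 18 added, the smooth muscle-like difference was -8.73 percentage points (exact p = 0.6) in place of -18.5, and the groups overlapped. Over the share alternatives, all other differences kept their sign.

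List medians changed sign with pigs left out as follows, lowest to highest. In smooth muscle-like nuclei they ran from -0.13 to 0.15 for SMC contractile, -0.20 to 0.0301 for osteochondrogenic, -0.38 to 0.061 for interstitial matrix, -0.31 to 0.0443 for fatty acid uptake and -0.31 to 0.33 for oxidative phosphorylation genes. In fibroblast-like nuclei they ran from -0.27 to 0.22 for SMC contractile, -0.12 to 0.58 for osteochondrogenic, -0.25 to 0.0588 for basement membrane, -0.37 to 0.0318 for cholesterol synthesis, -0.024 to 0.58 for LXR and -0.25 to 0.0854 for oxidative phosphorylation genes. In endothelial-like nuclei they ran from -0.15 to 0.31 for the TGF-beta list, -0.17 to 0.40 for the unfolded protein response and -0.00382 to 0.54 for insulin genes. In macrophage-like nuclei they ran from -0.0282 to 0.87 for SMC modulation, -1.66 to 0.0202 for basement membrane, -0.51 to 0.00289 for fatty acid oxidation, -0.11 to 1.71 for the unfolded protein response and -0.23 to 0.71 for oxidative phosphorylation genes. Of these 19, only basement membrane genes in macrophage-like nuclei were called with all pigs.

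Single genes that turned with pigs left out were list members named for their expression and not past any threshold. In smooth muscle-like nuclei SOX5 ran from -0.16 to 0.13, SOX6 from -0.40 to 0.0155, ELN from -0.40 to 0.39, COL4A1 from -0.0882 to 0.69, COL4A2 from -0.24 to 0.37, EIF2AK2 from -0.24 to 0.19 and RPS24 from -0.12 to 0.21. In fibroblast-like nuclei TRPS1 ran from -0.13 to 0.28 and SOX5 from -0.17 to 0.17, and in endothelial-like nuclei HERPUD1 from -0.24 to 0.30. In macrophage-like nuclei FN1 ran from -0.0293 to 0.89, COL4A1 from -1.61 to 0.70, COL4A2 from -1.94 to 0.44, ACADM from -0.42 to 0.62, DECR1 from -0.60 to 0.31, LTBP1 from -2.42 to 0.49, DNAJC3 from -0.51 to 0.55, NDUFS4 from -0.96 to 0.71, FOSB from -1.20 to 0.40, RPS24 from -0.56 to 0.036 and CIITA from -1.80 to 0.92. NDUFV2 ran from -0.37 to 10.15 and RPS9 from -0.85 to 9.45, and the high ends are fitted values against a lone control pig with 0 counts and bound nothing.

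Other alternatives turned these genes. With no filter on low counts they were COL4A2 (-0.00623) in smooth muscle-like, HERPUD1 (-0.096) in endothelial-like, and COL4A1 (0.26), ACADM (0.15), DNAJC3 (0.0561) and RPS9 (0.11) in macrophage-like nuclei. With a stricter filter on low counts they were SOX5 (0.0278), ELN (0.0477) and EIF2AK2 (0.0125) in smooth muscle-like, SOX5 (0.000103) in fibroblast-like and COL4A1 (0.12) in macrophage-like nuclei. With limma-voom they were SOX5 (0.0076) in fibroblast-like and FN1 (-0.23) and RPS9 (0.26) in macrophage-like nuclei. ELN in smooth muscle-like nuclei turned with a stricter filter on nuclei (0.00872), a Leiden resolution of 0.5 (0.0368), centring per library (0.00168), the ambient filter (0.00547), low-marker clusters added (0.00413) and nuclei of at least 2000 UMIs (0.00616). COL4A2 there turned at a resolution of 0.5 (-0.11) and when centred (-0.00954), SOX5 with nuclei of at least 2000 UMIs (0.0745), and PRR16 in pericyte-like nuclei at a resolution of 0.5 (-0.24). Centring turned COL4A1 (0.72), COL4A2 (0.21), ACADM (0.21), DECR1 (0.23), ZEB1 (0.33), DNAJC3 (0.20), NDUFV2 (-0.0803) and FOSB (0.0957) in macrophage-like nuclei. With no doublet removal CALD1 (-0.0167) in fibroblast-like and COL4A1 (0.30) in macrophage-like nuclei turned, and with the ambient filter SOX5 (0.00689) in fibroblast-like nuclei.

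Single clusters turned POSTN (0.0306) and HERC6 (-0.21) in cluster 7, CALD1 (-0.0437), EIF2AK2 (0.58) and SDHB (0.28) in cluster 13, HERPUD1 (-0.36) in cluster 15 and COL4A1 (0.0985) in cluster 9. In cluster 17 alone ACTA2 (-0.0412), LAMA3 (-0.14), TGFB2 (0.12), TGFBR3 (-0.30), DNAJC3 (0.41), SDHB (0.0354) and HK1 (-0.0495) turned, of which LAMA3, TGFB2 and TGFBR3 were called in the class. The macrophage-like class had 58780 and 41593 UMIs in the control pigs and a biological coefficient of variation of 0.416, the highest of all classes. In simulated counts 7.98% of genes changed by a log2 fold change of 2 were recovered there, and depth and spread were not separated.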

Other observations

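The tests in this part were all chosen after the results they concern were seen, and the test of SPP1 replaced earlier ones on marker percentages and on the order of classes after their values had been seen.

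SPP1 rose in smooth muscle-like nuclei of obese pigs, where macrophage markers had a positive median difference with 0 of 10 past the threshold, so free RNA from macrophages was tested as a candidate explanation. Free RNA of equal weight in all classes of a pig would make SPP1 agree between smooth muscle-like, fibroblast-like and endothelial-like nuclei within counting noise. That held in 1 of 3 obese pigs by a chi-square test of counts (p = 0.00323, 4.94e-13 and 0.19 in obese replicates 1 to 3). Replicate 3 had only 9 and 3 counts in the last 2 classes. Its ratio of highest to lowest CPM, taken without TMM factors, was 1.74, against 1.72 in replicate 1, so its agreement shows little. With TMM factors, SPP1 was at 17.6, 41.2 and 5.51 CPM in smooth muscle-like, 31.0, 52.3 and 10.1 in fibroblast-like and 32.1, 117 and 10.5 in endothelial-like nuclei. Smooth muscle-like nuclei were the lowest in each pig. Free RNA that weighs more in nuclei with fewer UMIs, and expression by the cells of each class, cannot be told apart, since no empty droplets were used here. Free RNA stays open for SPP1 in the other classes too. The earlier look gave smooth muscle-like as a percentage of macrophage-like CPM, at 2.44%, 5.01% and 0.363% for SPP1 and 1.29%, 3.27% and 0.592% for CD163 in obese replicates 1 to 3. Other markers lay from 0.119% for SLC11A1 to 29.3% for MERTK, both in obese replicate 3, so it decided nothing.

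The list of cholesterol synthesis genes was lower in smooth muscle-like nuclei of obese pigs, whose nuclei also held fewer UMIs. Lower depth per nucleus would predict a median near 0 among nuclei of 1000 to 2000 UMIs, where the mean was 1456, 1465 and 1433 UMIs in obese and 1490 and 1509 in control pigs. The median there was -1.14 over 16 members (-1.42 to -0.954 with each pig left out), against -1.18 over all nuclei of the class, which argues against depth as the whole cause. This test replaced one on nuclei of at least 2000 UMIs, which hold most of the UMIs of the class. A difference in tissue handling between the groups would reach all cells of a piece of tissue. The one other class with enough members was fibroblast-like nuclei, at a median of -0.262, which lies on the same side and was not called, so handling and diet cannot be told apart because each group was one diet. A response of smooth muscle cells to the diet stays open and untested, and sterol levels of the same aortae, not used here, would help to test it. No test compared the list between the classes. The smooth muscle-like clusters took different shares in each group, as given above. That mix was not tested as a cause of the fall of SREBF2 or of the list.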
